A study of Mus musculus with 6 samples.

How the data were processed

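Total RNA of 6 subcutaneous B16 tumors was profiled by RNA sequencing. B16 is a melanoma cell line of the C57BL/6 mouse, and the tumors were grown in mice of that strain. About 100000 cells, either with a knockout of ATM or carrying a vector control, were injected per the labels' protocols, and tumors were collected on day 13. The labels give 3 vector control tumors and 3 ATM knockout tumors, numbered 1 to 3 in each group. They do not say whether each tumor came from its own mouse, how ATM was disrupted, or whether the knockout cells were a clone or a pool. The p-values therefore measure the spread between these 6 tumors, and genotype cannot be separated from the cell line that carries it.

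The deposited files hold raw counts per gene, 1 library per file. Trim Galore, cutadapt, STAR, SAMtools and HTSeq are named without versions, roles or order, and the builds as GRCm38 and mm10, per the submitters' processing notes. The strand setting of the counting is not given in the sources used here, so whether reads of overlapping and antisense genes were told apart is not known. All 55536 gene identifiers, with their versions and symbols, matched the GENCODE M21 primary assembly annotation, which supplied the GRCm38 coordinates. Rows that name no gene were left out of library sizes and tests. Reads outside any annotated gene were 16.7% to 18.2% of the reads listed per library, and reads falling on several genes were 1.21% to 1.38%. The counters for unaligned, low-quality and multiply aligned reads are listed at 0 in all 6 files, so reads shared by near-identical copies may be missing from the counts. The mitochondrially encoded mRNAs mt-Co2, mt-Atp8, mt-Atp6, mt-Nd3 and mt-Nd4l are listed at 0 in every library and mt-Co3 at no more than 1 count, and no level is given for these 6.

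Counts on genes summed to 23613121, 22101124 and 24165801 in vector control tumors 1, 2 and 3 and to 23663109, 27630725 and 29037715 in ATM knockout tumors 1, 2 and 3, which sets the precision of single genes together with the spread between tumors. No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom 21.1 to 80.2), so each library counted as 1 sample. Correlations of log2 CPM between libraries lay between 0.931 and 0.968 among the vector control tumors, between 0.976 and 0.989 among the ATM knockout tumors and between 0.937 and 0.976 across the groups. Vector control tumor 3 correlated more with ATM knockout tumors 1, 2 and 3 (0.973, 0.976 and 0.970) than with vector control tumors 1 and 2 (0.931 and 0.968), so the libraries did not group by genotype alone.

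Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which kept 15696. Library sizes were scaled by TMM, with factors from 0.959 to 1.03, and each gene was tested with the quasi-likelihood F test with robust dispersions and genotype as the term. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. The common biological coefficient of variation was 27.6%. Levels are TMM-scaled CPM, given as mean ± SD of 3 tumors, and log2 fold changes are ATM knockout minus vector control, ± SE. On simulated counts for this comparison, with 200 genes changed and 15430 passing the filter, the test recovered 47% of genes changed 2-fold and 82.3% of genes changed 4-fold, none in the wrong direction. It also called 14 unchanged genes among 140 calls, a larger share than the threshold aims at.

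32 gene lists covering pathways, cell types and sample handling were fixed before the data were examined, as were the groups, tests, alternatives and the rule for naming genes. List members present under 2 symbols were counted once. Lists with at least 5 tested members, 31 of the 32, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), again adjusted over the lists. List levels per tumor are the mean log2 CPM over tested members. They were compared with a two-sided exact permutation test over the 20 assignments of 6 tumors, whose smallest possible p is 0.1, so that test cannot pass 0.05. Genes were named by 3 rules: 16 fixed genes; the 8 higher and 8 lower genes with the largest fold among those with an adjusted p below 0.05, a mean of at least 2 CPM and groups that do not overlap, without predicted genes and pseudogenes; and up to 4 members of each list with the smallest p, with called members also named where they number 5 or fewer. Genes named outside this rule are said to be so. Of the genes the rule names, 1 is not reported here, and the text prints examples of the others.

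The replicate numbers are not stated to pair tumors. Alternatives were size factors by median ratio or library size alone, no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, non-robust dispersions, a replicate block, protein-coding genes only, removal of keratinocyte, muscle, adipocyte and erythroid list genes, thresholds of 0.01 and 0.10, a 2-fold minimum, an estimated correlation or fry for lists, and each library left out in turn. A limma-voom fit with library quality weights was added after the data were seen. Computation used R 4.3.3 and Python 3.11.15.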

Results

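Gene expression was measured in 6 mouse melanomas grown under the skin from B16 cells, 3 from vector control cells and 3 from ATM knockout cells. ATM is the kinase that signals DNA double-strand breaks. The title of the series places the experiment in work on loss of ATM, escape of mitochondrial DNA into the cytosol, sensing of that DNA by cGAS and STING, and immunotherapy. The comparison therefore asks how tumors of ATM knockout cells differ from tumors of control cells in the transcripts of tumor and host cells together. Each library held between 22101124 and 29037715 counts on annotated genes, and 15696 genes had enough counts to be tested.

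Atm itself (chromosome 9, 53439149 to 53536740, GRCm38) was read at similar levels in both groups. Its level was 105 ± 8.09 CPM in vector control tumors and 112 ± 18.0 CPM in ATM knockout tumors (SD, n = 3 per group), a log2 fold change of 0.10 ± 0.13 (SE; edgeR adjusted p = 0.707). Single tumors held 2508, 2346 and 2306 Atm counts in the control group and 2371, 3692 and 3132 in the knockout group. Without ATM knockout tumor 2 the fold change was -0.03. Counts over a whole gene do not show whether its protein is made, host cells carry an intact Atm, and the disrupted part of the gene is not stated, so these values do not check the genotype labels.

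Cgas and Tmem173, genes of the sensing pathway named in the series title, and Tfam, a gene of mitochondrial DNA maintenance, did not pass the edgeR test. Cgas, the cytosolic DNA sensor, was at 14.5 ± 1.04 CPM in control and 19.6 ± 3.36 CPM in knockout tumors (log2 fold change 0.44 ± 0.15, adjusted p = 0.145), with the 2 groups not overlapping. Tmem173, which encodes STING, was at 71.5 ± 11.2 and 71.9 ± 6.22 CPM, and its difference of 0.01 took the other sign without vector control tumor 2 (-0.08), ATM knockout tumor 1 (-0.05) or ATM knockout tumor 3 (-0.01). Tfam, which packages mitochondrial DNA, was at 53.4 ± 0.812 and 50.4 ± 5.08 CPM. Ifnb1, the gene of interferon beta, had 2, 3 and 1 counts in the control tumors and 0, 0 and 1 in the knockout tumors, too few to test. Of 19 tested nucleic acid sensing genes 1 fell, Tlr3, a receptor for double-stranded RNA, from 125 ± 22.2 to 75.5 ± 4.62 CPM (-0.72 ± 0.13, adjusted p = 0.0396). The other 18 did not pass in edgeR, among them the interferon receptor genes Ifnar1 (-0.24) and Ifnar2 (-0.39) and the adaptor Mavs (0.29). DESeq2 called these 3 as well as Tlr3, 1 higher and 3 lower in all, and limma-voom called Tlr3 alone. Adjusted over the list alone, 1 member rose and 3 fell. The list as a set was not called (camera adjusted p = 0.902), and its mean of 0.02 and the direction of the set test differ in sign.

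Type I interferon-stimulated genes were lower in ATM knockout tumors as a set by camera at its preset correlation, a call lost with an estimated correlation. Camera called 8 lists in all, and 4 to 20 in the 9 other splits of the tumors into groups of 3. In 7 of those splits it called more than 8, so this and the other list calls do not set genotype apart from other groupings. Of 42 tested members 5 fell and none rose, both over all genes and adjusted over the list alone (DESeq2 called 10 lower). Ifi44 fell from 80.4 ± 16.9 to 38.1 ± 7.40 CPM (log2 fold change -1.08 ± 0.19, adjusted p = 0.0396), and Oas1g from 26.8 ± 2.51 to 13.8 ± 1.33 CPM (-0.95 ± 0.12, adjusted p = 0.0176). Oas2 (-1.04) and Oas1a (-0.55), further 2'-5' oligoadenylate synthetase genes, and Irf9 (-0.57), a subunit of the factor that binds interferon-stimulated promoters, completed the 5. Members of the Oas1 family are similar in sequence, so the split of reads between them is uncertain. Irf9 lies on chromosome 14 and Tlr3 on chromosome 8, where most expressed genes were lower in the knockout tumors (medians -0.37 and -0.26). Oas1g, Oas1a and Oas2 lie together on chromosome 5, between 120 and 130 Mb, where the median over expressed genes was -0.20. Isg15 (131 ± 26.3 and 93.1 ± 18.5 CPM) and Ifit1 (106 ± 42.8 and 71.4 ± 13.1 CPM) did not pass. The list mean was -0.33, with 5 of 42 members above 0, and the set was called by camera (adjusted p = 9.1e-05) but not with its genes' own correlation (adjusted p = 0.947 with an estimated correlation). List levels per tumor overlapped (6.79 ± 0.179 and 6.48 ± 0.222, exact permutation p = 0.2), and without vector control tumor 1, the tumor with the highest level, the mean was -0.21.

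The genes of the response to interferon gamma took no common direction. None of 30 passed the edgeR test, adjusted over the list alone included, 1 was higher and 1 lower at an unadjusted p below 0.05, and DESeq2 called 1 lower. The set was not called (camera adjusted p = 0.834), with a mean of -0.0039 and a median of 0.03. The chemokine gene Cxcl10 was at 239 ± 59.7 CPM in control and 121 ± 18.3 CPM in knockout tumors (-0.99 ± 0.21, adjusted p = 0.0525), while its neighbor Cxcl9 was at 144 ± 11.2 and 192 ± 37.2 CPM (0.41 ± 0.14, adjusted p = 0.155). Cd274, which encodes PD-L1, was at 218 ± 113 and 167 ± 33.1 CPM, and its fold change of -0.39 became 0.12 without vector control tumor 1. None of the 22 MHC class I presentation genes passed, Tapbp (0.55) and Tap2 (0.61) being among those with the smallest p, and the set was not called (adjusted p = 0.175). Here 4 members were higher and 1 lower at an unadjusted p below 0.05, DESeq2 called 4 higher and 1 lower, and the set was called without ATM knockout tumor 2 (0.26).

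**Figure D1:**
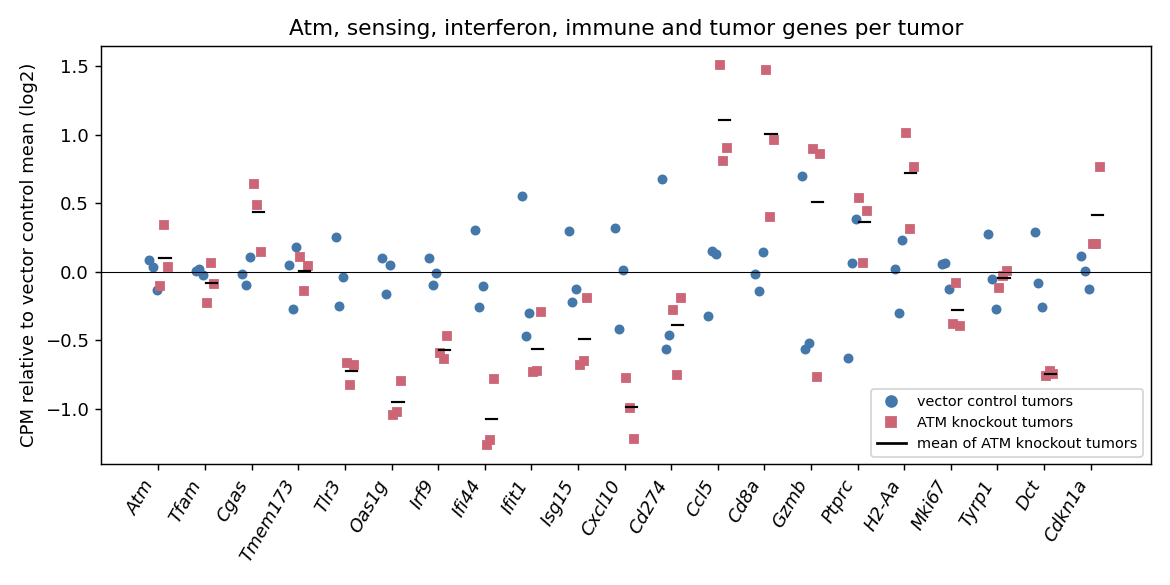
CPM of 21 named genes in each tumor relative to the vector control mean (log2 axis), with circles for vector control tumors 1 to 3, squares for ATM knockout tumors 1 to 3 and a line at the ATM knockout mean. The groups overlap for Atm, whereas all 3 knockout tumors lie below all 3 control tumors for Tlr3, Oas1g, Irf9, Ifi44, Cxcl10 and Dct and above them for Ccl5.

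T cell transcripts were higher in ATM knockout tumors as a set by camera at its preset correlation, a call lost with an estimated correlation, and no single one passed in edgeR. Of 24 T cell genes 23 had a positive log2 fold change, 13 of them with an unadjusted p below 0.05, and none passed in edgeR over all genes or adjusted over the list alone, while DESeq2 called 5 higher. Cd8a, a co-receptor chain of cytotoxic T cells, was at 10.5 ± 1.07 CPM in control and 21.1 ± 7.65 CPM in knockout tumors (log2 fold change 1.01 ± 0.27, adjusted p = 0.0883). Cd8b1 (0.91) and Cd3d (0.98) were among the other members with the smallest p. The list mean was 0.76 and the set was called (camera adjusted p = 7.87e-06; adjusted p = 0.947 with an estimated correlation). Levels per tumor were 1.78 ± 0.307 and 2.499 ± 0.50 log2 CPM (exact permutation p = 0.2), and ATM knockout tumor 2 lay within the control range. The call held without each library in turn, with the mean at 0.47 without ATM knockout tumor 1.

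Of the cytotoxic effector genes, Ccl5 rose and the other 19 did not pass in edgeR. Ccl5, a chemokine made by activated T and NK cells, rose from 8.46 ± 1.47 to 18.2 ± 5.07 CPM (1.11 ± 0.23, adjusted p = 0.0495), whereas Gzmb, which encodes granzyme B, was at 22.6 ± 12.3 and 32.2 ± 16.4 CPM (adjusted p = 0.666). The call of Ccl5 ended with limma-voom (adjusted p = 0.0679), with library size as the only scaling (0.0506) and with non-robust dispersions (0.0543), while DESeq2 kept it. The set was called (mean 0.29, camera adjusted p = 0.0197; adjusted p = 0.947 with an estimated correlation). That call ended with library size as the only scaling (mean 0.34) and without vector control tumor 2 (0.17), ATM knockout tumor 1 (0.12) or ATM knockout tumor 3 (0.21), and the mean was 0.57 without vector control tumor 1, 0.46 without ATM knockout tumor 2 and 0.64 when genes had to reach 1 CPM in 3 libraries (camera adjusted p = 0.0128). MHC class II genes, none of 11 passing in edgeR singly or adjusted over the list alone (6 with an unadjusted p below 0.05, 4 called higher by DESeq2), were also called (mean 0.37, camera adjusted p = 0.0122; adjusted p = 0.947 with an estimated correlation). H2-Aa was at 479 ± 87.0 and 790 ± 186 CPM and H2-DMa at 65.6 ± 12.2 and 123 ± 29.1 CPM. Both lie, as Tapbp and Tap2 do, between 30 and 40 Mb of chromosome 17, where the median over expressed genes was 0.20. The class II call ended without vector control tumor 1 (0.25) or vector control tumor 2 (0.46), and the mean was 0.20 without ATM knockout tumor 1. Adjusted over the list alone, 1 cytotoxic gene rose.

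Other immune lists were not called. T cell checkpoint genes (mean 0.35, camera adjusted p = 0.101) and NK cell genes (0.44, 0.0907) had no passing member in edgeR, and Pdcd1, which encodes PD-1, was at 5.89 ± 1.13 and 10.7 ± 3.58 CPM. Unadjusted p-values lay below 0.05 for 3 and 1 of their members, and DESeq2 called 2 and 1 higher. Of the regulatory T cell genes (0.05, adjusted p = 0.834) none passed in edgeR or DESeq2 or had an unadjusted p below 0.05. Of the dendritic cell genes (-0.05, adjusted p = 0.310) none passed in edgeR, 2 were higher at an unadjusted p below 0.05 and DESeq2 called 1 higher. In monocyte and macrophage genes the mean was -0.10 (adjusted p = 0.836). B and plasma cell genes had negative fold changes in all 9 tested members (mean -1.45, camera adjusted p = 0.0533). Neutrophil genes had them in 11 of 12 (-1.005, 0.0907). Again none passed in edgeR, 4 and 1 had an unadjusted p below 0.05, and DESeq2 called 1 and 0. The B and plasma cell level was 0.117, 2.558 and 1.127 log2 CPM in vector control tumors 1, 2 and 3. In ATM knockout tumors 1, 2 and 3 it was 0.367, 0.241 and 0.27, so the groups overlapped (exact permutation p = 0.4). Neutrophil levels overlapped as well (exact permutation p = 0.2). Of 16 pan-leukocyte genes 1 fell, Arhgdib, from 470 ± 13.0 to 341 ± 30.5 CPM (-0.46 ± 0.09, adjusted p = 0.0394). Yet 14 of the 16 had a positive fold change, and the set was not called (mean 0.15, camera adjusted p = 0.348). Ptprc, which encodes the leukocyte antigen CD45, was at 100 ± 33.4 and 129 ± 21.4 CPM. Relative to the pan-leukocyte level the T cell level differed by 0.50 (exact permutation p = 0.2), the B and plasma cell level by -1.20 and the neutrophil level by -0.97, each of the latter 2 with an exact permutation p of 0.1, the smallest that 3 against 3 can give. Of 29 chemokine and cytokine genes Ccl5 rose in edgeR, DESeq2 called 2 higher and 2 lower and limma-voom none, 1 further member fell adjusted over the list alone, and the set was not called (adjusted p = 0.639). Some of these lists were called without 1 tumor: B and plasma cell (-1.85), neutrophil (-1.21) and macrophage genes (-0.35) without vector control tumor 1, NK cell (1.01), B and plasma cell (-1.58), dendritic cell (0.44) and pan-leukocyte genes (0.50) without vector control tumor 3, checkpoint (0.52) and NK cell genes (0.60) without ATM knockout tumor 2, and neutrophil genes (-1.41) without ATM knockout tumor 3. With library size as the only scaling B and plasma cell (-1.41) and neutrophil genes (-0.97) were called, and without a filter on low counts checkpoint (0.36), NK cell (0.46), B and plasma cell (-1.74) and neutrophil genes (-1.33). In the set tests of the interferon gamma, macrophage, dendritic cell and fibroblast lists, as in nucleic acid sensing, the direction of the test differed in sign from the mean fold change.

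Markers of tissue around the tumor differed widely between single tumors. Skeletal muscle levels were 0.93, 1.77 and 7.88 log2 CPM in vector control tumors 1, 2 and 3 and 6.70, 8.57 and 5.30 in ATM knockout tumors 1, 2 and 3. No muscle gene passed in edgeR (1 with an unadjusted p below 0.05, 1 called higher by DESeq2). The set was called (mean 1.13, camera adjusted p = 0.00591, and 0.947 with an estimated correlation). That call ended without vector control tumor 1 (0.59) or vector control tumor 2 (0.58), while the mean was 5.98 without vector control tumor 3. Without ATM knockout tumor 2 the set was still called as higher (camera adjusted p = 0.0335), although its mean was then -0.10. Fibroblast and matrix genes were at 3.58 log2 CPM in vector control tumor 1 and 5.70 to 6.62 in the other 5, and adipocyte genes ranged from -0.65 to 5.01 within the control group. Endothelial genes were lower in knockout tumors as a set (mean -0.43, adjusted p = 0.00591; adjusted p = 0.947 with an estimated correlation), with none of 16 passing in edgeR, 6 lower and 1 higher at an unadjusted p below 0.05, 3 called lower by DESeq2 and 1 above 0. Cdh5, the cadherin of endothelial junctions, was at 60.1 ± 13.2 and 40.6 ± 5.80 CPM (log2 fold change -0.56), and lies between 100 and 110 Mb of chromosome 8, where the median over expressed genes was -0.29. That call held without each library, with the mean at -0.17 without vector control tumor 3. Erythroid (camera adjusted p = 0.514), fibroblast (0.750) and adipocyte genes (0.175) were not called, although fibroblast (-0.62) and adipocyte genes (-2.66) were without vector control tumor 1 and erythroid genes (-3.57) without ATM knockout tumor 3, and only 3 of 16 keratinocyte genes were expressed enough to test.

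**Figure D2:**
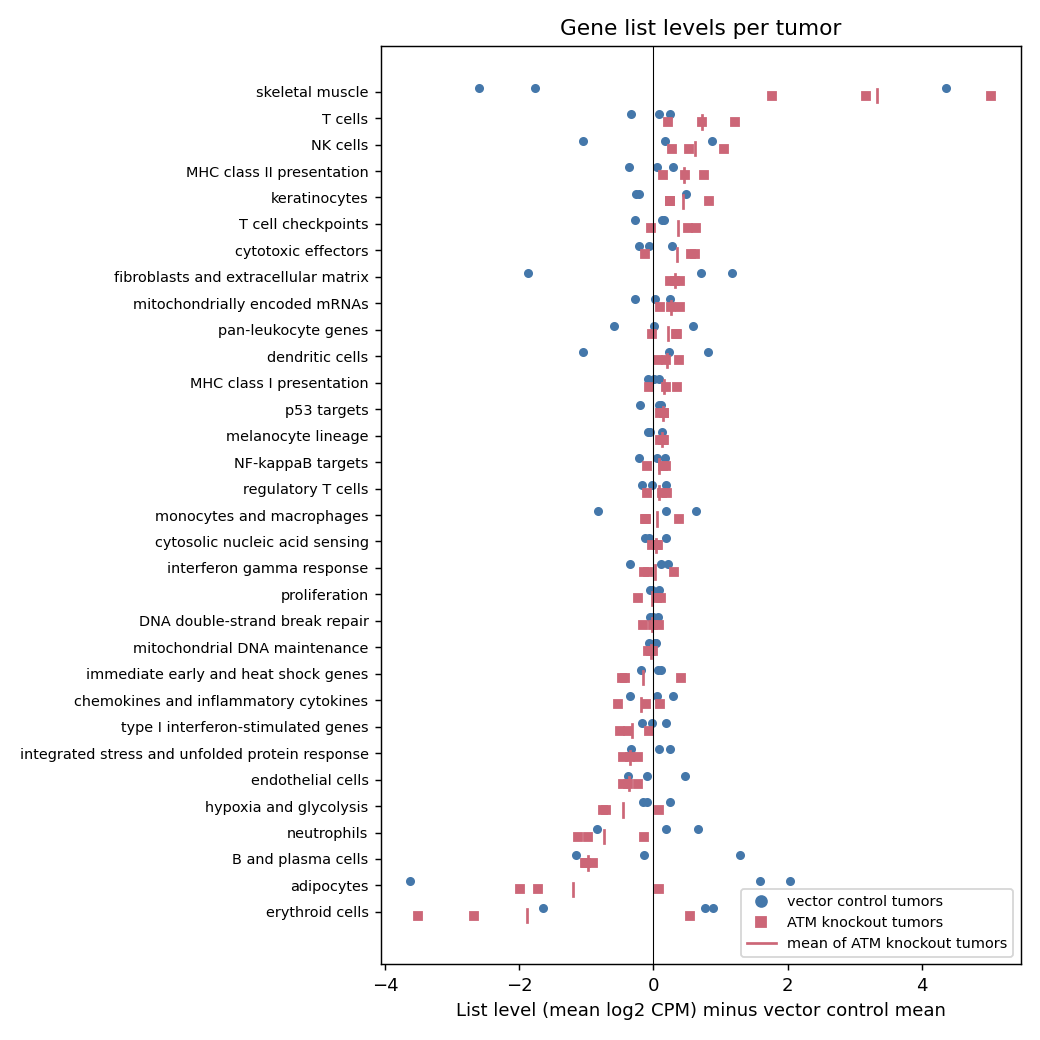
Level of each of the 32 gene lists per tumor, as the mean log2 CPM over tested members minus the mean of the vector control tumors (circles, vector control; squares, ATM knockout; line, mean of the ATM knockout tumors). Skeletal muscle, adipocyte and erythroid levels spread widely within groups, while the T cell level of ATM knockout tumor 2 (2.00) lies within the control range of 1.44 to 2.03.

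Over all genes, 347 were higher and 431 lower in ATM knockout tumors, and 94 and 96 of these changed at least 2-fold. Among genes with a mean of at least 2 CPM, predicted genes and pseudogenes aside, the largest increases were in Gpm6a, a membrane glycoprotein of neurons (chromosome 8, 54954843 to 55060871), from 0.213 ± 0.370 to 25.4 ± 3.84 CPM (log2 fold change 6.90 ± 1.09, adjusted p = 0.0350), in Cdhr2, a protocadherin of the brush border (chromosome 13, 54701461 to 54736662), from 1.44 ± 0.826 to 42.4 ± 4.06 CPM (4.88 ± 0.48, adjusted p = 0.0130), and in Kcnj13, an inward-rectifying potassium channel (chromosome 1, 87386363 to 87394729), from 2.93 ± 1.74 to 84.4 ± 24.0 CPM (4.84 ± 0.57, adjusted p = 0.0218). The control level of Gpm6a came from vector control tumor 2 alone (0.640 CPM, and 0 in the other control tumors), so its fold change rests on that library. Without it the fitted value was 12.36, which depends on the prior count, and with limma-voom it was 8.55. Zswim5 (4.13), B4galnt4 (3.73), Pard6g (3.72), Gspt2 (3.57) and Miga1 (3.57), the last a gene of mitochondrial fusion, followed. The largest decreases among the same kind of genes were in Prrg4 (chromosome 2, 104830741 to 104849876), from 7.50 ± 3.11 to 0.508 ± 0.0961 CPM (-3.88 ± 0.39, adjusted p = 0.010), and in the bicarbonate transporter gene Slc4a5 (chromosome 6, 83219828 to 83304945), from 17.1 ± 13.8 to 1.27 ± 0.390 CPM (-3.75 ± 0.65, adjusted p = 0.0395). The control level of Slc4a5 rested on vector control tumor 1 (33.0 CPM, against 7.77 and 10.6 in the other control tumors), and without it the fold change was -2.85, a smaller decrease than those of Ido2, Wfikkn2, Arnt2 and Fndc3c1 in the same fit. Ido2 (-3.22), which encodes a tryptophan-degrading enzyme, Wfikkn2 (-3.08), Fndc3c1 (-2.89), Ccdc149 (-2.73), Arnt2 (-2.71) and Tmlhe (-2.59, and -1.999 without vector control tumor 1) followed. Fndc3c1 was the most abundant of these, at 137 ± 8.87 CPM in control and 18.5 ± 3.84 CPM in knockout tumors. In all 778 called genes the groups did not overlap, as in 29.7% of all tested genes, against 10% by chance.

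The number of calls depended strongly on single libraries. Higher and lower genes numbered 587 and 622 without vector control tumor 1, 19 and 9 without vector control tumor 2, 55 and 55 without vector control tumor 3, 0 and 2 without ATM knockout tumor 1, 22 and 20 without ATM knockout tumor 2, and 97 and 99 without ATM knockout tumor 3. The 2 genes left without ATM knockout tumor 1 were Fndc3c1 (-2.73) and Mdm4 (-1.93), and 2472 genes then had an unadjusted edgeR p below 0.05. DESeq2 called 920 and 1150 with all libraries. With library size as the only scaling the split was 504 higher and 356 lower (58.6% higher, against 44.6%). None of the 778 genes changed sign under these settings, but the groups lie apart in all of them, so leaving out a tumor could hardly change a sign. Apart from Fndc3c1 and Mdm4, the called genes named here all lost their call without ATM knockout tumor 1. Without a filter on low counts the calls of Gpm6a (adjusted p = 0.0944), Kcnj13 (0.0515), Slc4a5 (0.109), Ifi44 (0.0551) and Oas2 (0.0648) ended, with limma-voom those of Slc4a5 (0.0734), Tmlhe (0.0513) and, as given beside them, Ccl5, Zmat3 and Gdf15, and with library size as the only scaling that of Arhgdib (0.0502) and that of Ccl5. Mdm4 was chosen after its values were seen.

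**Figure D3:**
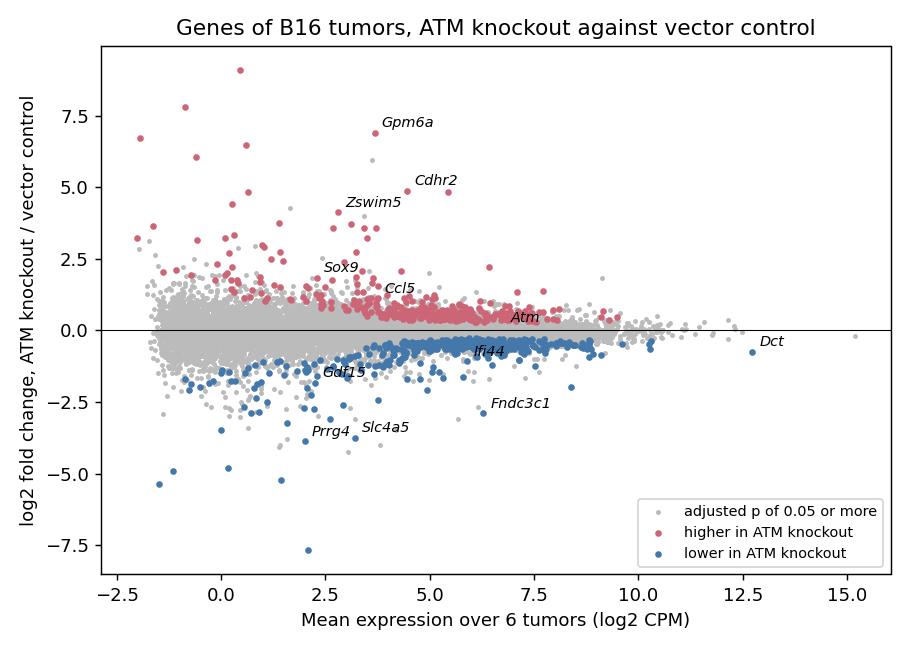
Log2 fold change between ATM knockout and vector control tumors against mean expression in log2 CPM for 15696 tested genes, with called genes colored by direction. Gpm6a (6.90) and Prrg4 (-3.88) mark the ends among labelled genes, and Atm (0.10) lies at the center.

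In the tumor cell lists few genes passed. Of 20 melanocyte lineage genes, Sox9, a transcription factor of the neural crest, rose from 2.13 ± 0.956 to 7.64 ± 0.690 CPM (1.84 ± 0.32, adjusted p = 0.0361), and Dct, an enzyme of melanin synthesis on chromosome 14, fell from 8521 ± 1703 to 5079 ± 64.3 CPM (-0.75 ± 0.15, adjusted p = 0.0434). Adjusted over the list alone, 4 rose and 2 fell, DESeq2 called 5 higher and 2 lower, and the set was not called (adjusted p = 0.344). Tyrp1, another melanin enzyme, was at 5800 ± 1128 and 5620 ± 248 CPM, and its fold change of -0.05 was 0.01 with library size as the only scaling and 0.12 without vector control tumor 1. Of 28 p53 targets Zmat3 rose (0.53 ± 0.11, adjusted p = 0.0493) and Gdf15 fell (-1.83 ± 0.35, adjusted p = 0.0411), 2 rose and 1 fell adjusted over the list alone, and 22 had a positive fold change (mean 0.11, camera adjusted p = 0.0519). DESeq2 called 5 of them higher and 1 lower and limma-voom none (adjusted p = 0.0577 for both Zmat3 and Gdf15), and Zmat3 also lost its call with non-robust dispersions (0.0513). Gdf15 lies between 70 and 80 Mb of chromosome 8, where the median over expressed genes was -0.23. The p53 set was called with all tumors when no filter on low counts was used (0.13, camera adjusted p = 0.0199), without vector control tumor 3 (0.18), ATM knockout tumor 2 (0.09) or ATM knockout tumor 3 (0.12), and the melanocyte set without vector control tumor 1 (0.20). The cell cycle inhibitor Cdkn1a was at 152 ± 12.8 and 202 ± 48.2 CPM (adjusted p = 0.213). Of 28 double-strand break repair genes Atr, the kinase related to ATM, fell from 72.9 ± 4.18 to 53.3 ± 4.68 CPM (-0.45 ± 0.09, adjusted p = 0.0424), also adjusted over the list alone, with the set not called (0.645). None of 28 proliferation genes passed in edgeR (set adjusted p = 0.645), with 4 higher and 4 lower at an unadjusted p below 0.05 and 2 called higher and 1 lower by DESeq2, and Mki67 was at 511 ± 37.2 and 421 ± 54.1 CPM.

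Metabolic and stress lists were lower or without a call. Hypoxia and glycolysis genes were lower as a set (mean -0.42, camera adjusted p = 0.00591; adjusted p = 0.947 with an estimated correlation), with none of 24 passing in edgeR or DESeq2 and 4 lower at an unadjusted p below 0.05. Ero1l, an oxidase of protein folding, was at 508 ± 67.6 and 215 ± 118 CPM, and lies between 40 and 50 Mb of chromosome 14, where the median over expressed genes was -0.39. The call ended without vector control tumor 1 (-0.27) or ATM knockout tumor 1 (-0.28), and the mean was -0.75 without ATM knockout tumor 3, whose level of 6.99 log2 CPM lay within the control range of 6.76 to 7.16. Integrated stress and unfolded protein response genes were lower as a set (-0.36, adjusted p = 0.0102; adjusted p = 0.947 with an estimated correlation), the call ending without vector control tumor 2 (-0.21). None of the 22 passed in edgeR over all genes, 4 fell adjusted over the list alone, 8 were lower at an unadjusted p below 0.05 and DESeq2 called 6 lower. Asns, which makes asparagine, was at 212 ± 53.6 and 123 ± 9.27 CPM, and Mthfd2, of mitochondrial folate metabolism, at 203 ± 42.7 and 126 ± 12.8 CPM. All 7 tested mitochondrially encoded mRNAs had positive fold changes (mean 0.25, set adjusted p = 0.0907), with mt-Cytb at 3958 ± 786 and 5062 ± 447 CPM, none at an unadjusted p below 0.05 and none called by DESeq2. That set was called without vector control tumor 1 (0.38) or ATM knockout tumor 3 (0.32). Mitochondrial DNA maintenance genes (-0.05, 0.606) and NF-kappaB targets (0.06, 0.525) had no passing member in edgeR. At an unadjusted p below 0.05, 2 of the former were higher and 4 lower and 1 of the latter was higher and 2 lower, and DESeq2 called 1 of each lower. Of 17 immediate early and heat shock genes, which respond to tissue handling, Ier2 fell from 26.5 ± 0.378 to 15.2 ± 0.622 CPM (-0.80 ± 0.08, adjusted p = 0.010), and the set was not called (0.242), except without ATM knockout tumor 3 (-0.59). Ier2 lies between 80 and 90 Mb of chromosome 8, where the median over expressed genes was -0.35.

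Called genes were unevenly spread over the chromosomes. Chromosomes 8 and 14 held 8.7% of the tested genes and 213 of the 431 lower genes (49.4%), with 6 of the higher genes. Over expressed genes the median log2 fold change was -0.37 on chromosome 14 and -0.26 on chromosome 8. Chromosome 2, with 7.6% of the tested genes, held 70 of the higher and 19 of the lower genes. On the X chromosome, with 3.2% of the tested genes, 56 genes were higher and 30 lower. For the 118 expressed genes of the X chromosome beyond 130 Mb, levels were taken relative to each gene's mean over the 6 tumors and to the median of each library. Their median was -0.29 ± 0.02 in control and 0.30 ± 0.03 in knockout tumors (log2, SD, n = 3 per group), a difference of 0.595. For the 244 genes before this point it was 0.11 ± 0.02 and -0.10 ± 0.02, a difference of -0.208, the groups lying apart in both. This centering makes the group values mirror each other, so only their difference carries information. Further named genes lay in 10 Mb windows whose median had the sign of their own fold change, among them Mavs (window median 0.20), Cdkn1a (0.19), B4galnt4 (0.38), Asns (-0.16) and Fndc3c1 (-0.22). Others went against their window, among them Prrg4 (window median 0.26), Gspt2 (-0.24), Cgas (-0.18), Zmat3 (-0.16) and Mdm4 (0.08). How many named genes went each way was not counted, so no link of single genes to their windows is drawn. Over called genes, the median change of expressed neighbors within 5 Mb mostly had the sign of the gene's own change. It did so for 89.9% of 586 genes changed less than 2-fold and for 67.6% of 188 genes changed at least 2-fold. These chromosomes and the split at 130 Mb were chosen after the values were seen.

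**Figure D4:**
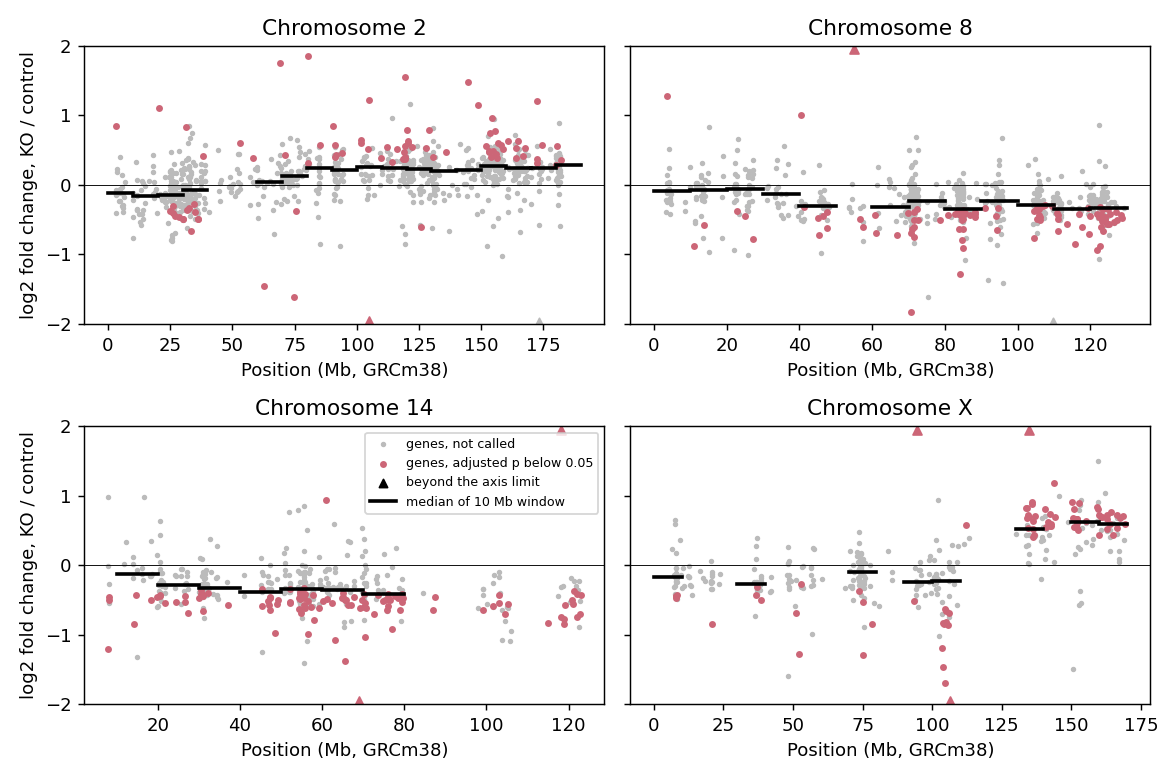
Log2 fold change of expressed genes along chromosomes 2, 8, 14 and X (position in Mb, GRCm38), with called genes colored, genes beyond the axis limits as triangles at the edge, and black bars for medians of 10 Mb windows with enough genes. The windows of chromosome 14 lie below 0 (median of its genes -0.37), and windows of the X chromosome beyond 130 Mb lie between 0.52 and 0.62.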

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

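The value below was picked after it was seen, among several measures of each library, and no test was run on it. With 3 tumors against 3, each such measure has a 10% chance of keeping its groups apart. Reads that fell on more than 1 annotated gene, which enter no comparison, made up 1.33% ± 0.049 of the reads listed in the ATM knockout tumors and 1.224% ± 0.012 in the vector control tumors (SD, n = 3 per group). The lowest knockout tumor (1.282%) lay above the highest control tumor (1.236%), which is why this share is given here.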

How the results depend on the processing

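The fit with library quality weights was chosen after the data were seen. DESeq2 called 920 higher and 1150 lower genes, and the weighted fit 1253 and 1373. An adjusted p of 0.01 left 26 and 22, one of 0.10 gave 783 and 916, and a 2-fold minimum left 94 and 96. Leaving out 1 tumor gave 0 to 587 higher and 2 to 622 lower genes. Same-numbered tumors did not deviate together (correlations 0.044, -0.272 and -0.42), and a replicate block gave 0 and 0 genes with 3004 at an unadjusted p below 0.05, while 11 lists were called, the 8 of all tumors and B and plasma cell (-1.09), neutrophil (-0.86) and p53 target genes (0.15), with the muscle mean at 4.46. Lists called as sets numbered 13 without a filter, 0 with an estimated correlation, 0 with fry, and 4 to 13 with 1 tumor left out. Set tests were not rerun for other tools and dispersions. The other scalings and filters, limma-voom, non-robust dispersions, protein-coding genes and removal of admixture genes kept both gene counts within 1.5 times. No called gene changed sign, which the groups lying apart in all of them largely fixes in advance. Some genes that passed no test with all tumors did change sign: with library size alone the log2 fold change of Tyrp1 was 0.0068, and with quality weights Cd274 was at 4e-04 and Tyrp1 at 0.0039. The macrophage set test took the other direction with library size alone (mean -0.0589) and at 1 CPM in 3 libraries (-0.075), the mean keeping its sign. With 1 tumor left out the log2 fold change lay between -0.0333 and 0.195 for Atm, -0.57 and 0.12 for Cd274, -0.15 and 0.12 for Tyrp1, and -0.0819 and 0.120 for Tmem173. The means of lists whose set test took the other direction without 1 tumor lay between -0.0256 and 0.137 for nucleic acid sensing, -0.16 and 0.13 for interferon gamma, -0.55 and -0.16 for chemokines, -0.0166 and 0.164 for regulatory T cells, -0.35 and 0.26 for macrophages, -0.36 and 0.44 for dendritic cells, -0.0922 and 0.502 for pan-leukocyte genes, -0.62 and 0.29 for fibroblasts, -0.0802 and 0.0405 for double-strand break repair, and -0.0869 and 0.0818 for proliferation. Each fit without a tumor also has fewer samples, and beyond that the cause was not tested.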

Other observations

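The genes and tests of this part were chosen after the results were seen, except the counts of calls over the splits of the tumors, the position test over all genes, the position test of vector control tumor 3, the tests without vector control tumor 1 and the whole-chromosome test of the interferon-stimulated genes. Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 3 fell in edgeR, Aars (-0.66), Gars (-0.50) and Iars (-0.53), and the others did not pass. At an unadjusted p below 0.05, 9 were lower and Hars (0.18) was higher, and 16 of the 20 had a negative fold change (median -0.17). Aars, Farsa (-0.35) and Kars (-0.27), all among the 9, lie on chromosome 8, whose median was -0.26. The 3 calls were lost without ATM knockout tumor 1, when 2 genes remained, Fndc3c1 (-2.73) and Mdm4 (-1.93), and those of Gars and Iars also with library size as the only scaling.

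The smallest p of all genes belonged to Mdm4, which encodes an inhibitor of p53 (chromosome 1, 132959484 to 133030561). It fell from 532 ± 39.9 CPM in vector control tumors to 135 ± 7.62 CPM in ATM knockout tumors (SD, n = 3 per group; log2 fold change -1.98 ± 0.09, edgeR adjusted p = 0.0029), and 22 of 28 p53 targets had a positive fold change without the set being called.

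Fold changes were clustered along chromosomes, since over 268403 pairs of genes 1 to 5 Mb apart, the correlation of log2 fold changes across genes, which are not independent replicates, was 0.1445 (upper bound over 1000 shuffles of gene positions, 0.0034), a value that segments at different copy number in the 2 cell lines may leave. For changes of 2-fold or more, the median change of neighbors within 5 Mb was 3.4% of the genes' own (upper bootstrap bound 4.5%), against 46.9% for smaller called changes. That argues against segments covering most of these neighbors as the source of the large changes. Shorter segments would leave the median of the neighbors unmoved and stay open. Uneven muscle content as the whole source is argued against, since the split of the tumors that follows the muscle level (vector control tumor 3 with ATM knockout tumors 1 and 2) kept its groups apart in 13.2% of all tested genes, though in 87.5% of the muscle genes, against 29.7% in the genotype split (SD over the other splits, 3.4). A contribution of muscle stays open, as vector control tumor 3 lay at 0.093 over the called genes, on a scale from the other control tumors (0) to the knockout mean (1), but calling genes whose groups lie apart (778 of 778) already places it there, so the bound set beforehand was wrong. Loss of ATM and separate histories of the lines are untested, and 10 splits of the tumors are too few for a share under 0.05 (347 higher and 431 lower genes in the real split, at most 0 in any other; 0 and 2 without ATM knockout tumor 1), the same correlation on differences of mean log2 CPM being 0.1199 in the real split and 0.0141 to 0.0494 in the others.

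T cell genes were called higher as a set in ATM knockout tumors by camera alone, with none of 24 passing singly in edgeR (13 at an unadjusted p below 0.05, 5 by DESeq2) and an adjusted p = 0.947 with an estimated correlation. Vector control tumor 1 as the only source is argued against, as the list mean without it was 0.615, or 81.1% of its value with all tumors. The camera call was also kept, but camera called lists in other splits of the tumors as well, so that call decides little. Relative to the endothelial level the T cell level differed by 1.075 with the groups apart. The endothelial list was chosen after it was seen to be lower, so this does not decide on a lower share of tumor cells. The T cell level differed by 1.462 relative to neutrophils (SD 0.466 in control and 0.674 in knockout tumors) and by 1.693 relative to B and plasma cells (SD 1.061 and 0.437), so transcripts of these lists did not rise with those of T cells. Both lists were chosen after they were seen to be lower, and lay at low levels (knockout means 0.219 and 0.293 log2 CPM). They therefore do not decide whether other kinds of leukocytes rose. Relative to macrophages the T cell level differed by 0.666 (SD 0.443 and 0.571) with the groups overlapping, so a joint rise of T cells and macrophages stays open. More T cells in knockout tumors stays an untested hypothesis, and without ATM knockout tumor 1 the mean fell to 0.47, further than without vector control tumor 1. The real split called 8 lists and 7 of the 9 other splits called more, up to 20, and whether a structure of the tumors other than genotype or the preset correlation of 0.01, below the estimated ones (0.038 to 0.931), lies behind this was not tested, while 10 splits are too few for a share under 0.05.

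Interferon-stimulated genes were called lower as a set in ATM knockout tumors by camera alone (adjusted p = 0.947 with an estimated correlation), and 5 of 42 fell singly. Camera called more lists in 7 of the 9 other splits of the tumors, so the set call decides little here too. Without vector control tumor 1 the list mean was -0.211, which is 63.9% of its value with all tumors and under the bound set beforehand, so that this tumor could be the source of part of the difference. Chromosome segments acting only on the members they carry are argued against as the whole source. The list mean was -0.302 with each member taken relative to its chromosome and -0.281 relative to its neighbors within 5 Mb (85.2% of the value). The neighbors of the 3 fallen Oas genes and of Oas3 nevertheless had a median of -0.19. These values cannot show whether a segment moved other members through Irf9, so that stays open. Irf9, on chromosome 14, was at -0.57, and at -0.20 relative to its chromosome. The pan-leukocyte level was 0.221 higher in the knockout tumors, the other way from what fewer leukocytes would give. That difference was smaller than the SD of 0.589 in the control tumors, so fewer leukocytes stay open. Loss of ATM stays open and untested.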
